A study of Escherichia coli with 8 samples.

How the data were processed

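The values analysed were FPKM for 4594 gene IDs in each of 8 libraries, as deposited by the authors. Per the submitters' processing notes, reads were aligned with Bowtie 1.0.0 and FPKM were computed with Cufflinks 1.3.0. The genome build and annotation are not given in the sources used here. Gene names came from the reference table of assembly ASM584v2, which holds no coordinates, and 4462 of the 4594 IDs (97.1%) were matched.

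Sequencing depth was recovered from low values, which fall on steps of single fragments. With the depth and fragment length that fit best, 97.7 to 99.1% of 209 to 321 low values per library were whole numbers of fragments within 0.1. By chance 20% would be at a fixed depth and fragment length. Both were chosen on the same values to make this share large, so 20% is not the chance level of the best fit. In a gene of 1 kb, 1 fragment corresponded to 0.152 to 0.235 FPKM and the floor of 3 fragments to 0.456 to 0.704 FPKM, which covers counting error only. Values summed to 6596150 to 9682540 FPKM per library, of which 71.1 to 84.8% lay in genes under 300 bases, so library scaling did not use the sum.

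Each library was divided by its median ratio to the geometric mean of all libraries over 2726 genes with 10 FPKM or more in all libraries. Genes with 5 FPKM or more in at least 2 libraries were tested, 3469 in all. limma with a trended variance prior was fitted to log2(FPKM + 1) of all 8 libraries at once, with 4 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method per comparison, with calls at adjusted p < 0.05. The comparisons were each deletion against WT and each pair of deletions.

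The fixed gene lists were tested with camera at a preset correlation of 0.01, and again with a correlation estimated per list. List p-values were adjusted over 29 lists per comparison. The test with an estimated correlation also rests on the 4 residual degrees of freedom, so its p-values can rise without correlated genes. In the oxyR deletion glycolysis had an estimated correlation of -0.0541, below 0.01, yet its adjusted p rose from 0.000689 to 0.0776. The lists covered the SoxRS and OxyR targets, iron-sulfur assembly, iron uptake, amino acid and nucleotide synthesis, central metabolism and respiration, stress responses, surface structures, ribosomal proteins, metals, thiol redox and the neighbours of the deleted genes. A gene can belong to more than 1 list, as poxB does in the SoxRS and RpoS lists, so results of different lists are not independent. The SoxRS and TCA cycle lists share fumC and acnA, and the OxyR-activated and Suf lists share suf genes. Genes named in the text are members of these lists, the largest changes of a comparison with a mean of at least 10 FPKM in 1 group, or genes picked after the values were seen, which are said to be so. The overlap of calls was set beside lists drawn independently and beside 100 simulations of unchanged groups that share simulated WT libraries.

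The groups, comparisons, gene lists, thresholds and most alternatives were chosen before the data were examined. Alternatives chosen after seeing the data were genes of 300 bases or more, limma-voom on estimated fragments, lists without the deleted genes, and the correlation of changes over genes above 0 in every library. The other alternatives were pseudocounts of 0.1 and 10, other filters, values as deposited, quantile normalization, only the 4 samples compared, the replicate number as a block, other variance priors, a doubling or halving, and leaving out each library. Alternatives planned for counts were not applied because the values are FPKM, and groups of 2 libraries are too small for a test of single libraries far from their group.

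The steps were tested on simulated data, in which 39 of 67 genes changed by 0.5 on the log2 scale were recovered (58.2%), 58 of 67 changed by 1 (86.6%) and 61 of 66 changed by 2 (92.4%), with 10 false calls, and none in a group left unchanged. Analyses ran in R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Reads were not used here.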

Results

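Transcript levels were measured by RNA sequencing in Escherichia coli K-12 MG1655, a laboratory reference strain, and in 3 strains derived from it that each lacked 1 regulator of the oxidative stress response. OxyR is a transcription factor that responds to hydrogen peroxide. SoxR is a sensor of redox-cycling compounds that switches on soxS, and SoxS is the transcription factor that then activates the superoxide response genes. Cells grew aerobically at 37 °C in minimal medium containing 0.2% glucose until mid-log phase and then received 250 µM paraquat, a redox-cycling compound that generates superoxide inside the cell, for 20 min. There were 2 libraries each of wild type (WT), the oxyR deletion, the soxR deletion and the soxS deletion, 8 in total. Each library held the wild-type or deletion strain under paraquat and untreated cells were not analysed here, so the comparisons are between strains under paraquat and none measures the response to paraquat itself. The labels do not say that the 2 libraries of a strain came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

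Depth, recovered from the steps between low values, was 7.72 and 7.94 M fragments in the WT libraries and 7.68 and 8.42 M in the oxyR deletion. It was 6.18 and 7.08 M in the soxR deletion and 5.6 and 7.88 M in the soxS deletion. The 2 libraries of a strain correlated at 0.992 to 0.995 across 2726 genes on the log2 scale. Their median absolute log2 difference was largest in WT, 0.113 against 0.0763 to 0.0830 in the deletions. The fit pooled the spread over all strains, so p-values of comparisons with WT may be too small. Levels below are deposited FPKM after library scaling, given as mean ± SD over n = 2 libraries, and log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. An exact 0 was not read as absence, because ssrA, an RNA that rescues stalled ribosomes in every cell, was listed at 0 in 1 library of the soxS deletion and at 1184600 FPKM in the other.

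The deleted genes matched the strain names in every library. In the oxyR deletion oxyR (b3961) stood at 0.404 ± 0.0767 FPKM (SD, n = 2), against 353 ± 8.51 in WT, 345 ± 21.4 in the soxR deletion and 363 ± 7.80 in the soxS deletion. In the soxR deletion soxR (b4063) was listed at 0 in 1 library and at 0.686 FPKM in the other, against 55.2 ± 5.34 in WT. The soxS gene (b4062) was listed at 0 in both libraries of the soxS deletion and stood at 19956 ± 364 FPKM in WT and 21659 ± 733 in the oxyR deletion. Without soxR, soxS fell to 570 ± 21.1 FPKM, a log2 change of -5.13 (adjusted p = 3.54e-07). In the soxS deletion soxR stood at 84.9 ± 0.693 FPKM, a log2 difference from WT of 0.62 that did not pass the test (adjusted p = 0.218). The list of the deleted genes and those next to them did not pass in any deletion against WT (adjusted p = 0.899, 0.0584 and 0.410 in the oxyR, soxR and soxS deletions), except in the soxR deletion without its library 2 (adjusted p = 0.0178). With the deleted genes taken out, adjusted p was 0.992, 0.400 and 0.731, though yjcB, near soxS, fell in both sox deletions (log2 -0.91 and -0.83).

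**Figure D1:**
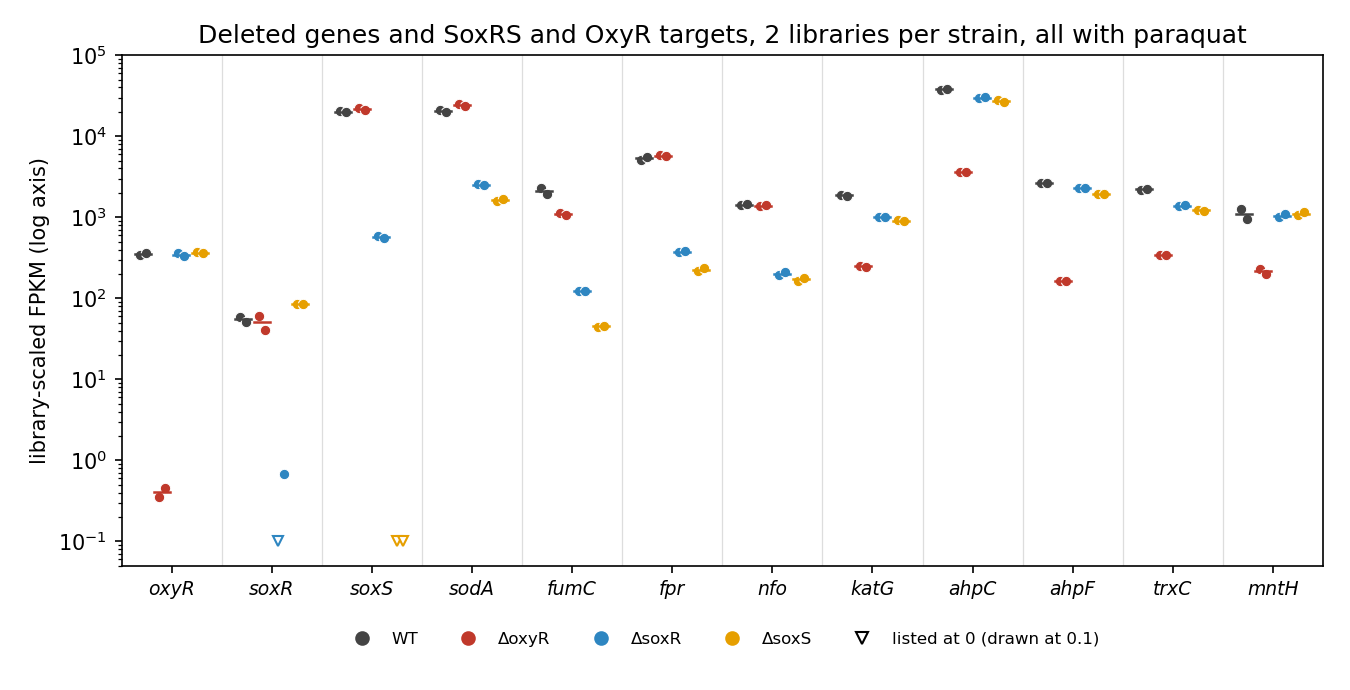
FPKM after library scaling (log axis) of oxyR, soxR, soxS and 9 genes of the oxidative stress response in each of the 8 libraries, with bars at the mean of the 2 libraries of a strain and open triangles for values listed at 0. The sodA, fumC, fpr and nfo points of both sox deletions lie below those of WT, while katG, ahpC, ahpF, trxC and mntH are lowest in the oxyR deletion, with ahpC at 3629 ± 39.7 FPKM there and 38006 ± 979 in WT (SD, n = 2).

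The oxyR deletion was compared with WT to ask which genes depended on OxyR under paraquat. The genes of hydrogen peroxide defence were far lower. The alkyl hydroperoxide reductase genes ahpC and ahpF fell from 38006 ± 979 to 3629 ± 39.7 FPKM and from 2648 ± 45.6 to 163 ± 1.67 FPKM (SD, n = 2), log2 changes of -3.39 and -4.01 (adjusted p = 4.04e-06 and 1.48e-07). The catalase gene katG fell from 1866 ± 46.7 to 249 ± 6.93 FPKM (log2 -2.90) and the glutaredoxin gene grxA from 1858 ± 39.5 to 76.6 ± 18.9 FPKM (log2 -4.60). The thioredoxin gene trxC (log2 -2.67) and the manganese importer gene mntH (log2 -2.35) fell as well. Among the 20 measured genes of the OxyR-activated list, 16 were lower and 1 was higher, and adjusted over the list alone 17 were lower and 1 higher. Adjusted p was 1.27e-10 for the list and 0.0391 with an estimated correlation. The higher one was dsbG, a periplasmic disulfide isomerase gene (log2 0.62). The small RNA gene oxyS was listed at 0 in both libraries of the oxyR deletion and at 30117 and 24874 FPKM in WT. Its call (adjusted p = 0.0469) was lost in 6 of 8 fits that left out 1 library, though its log2 change stayed between -14.9 and -14.6. In the soxR deletion the oxyS change ran from -14.8 to -0.488 over the same fits. The spread is pooled over all strains, so the lost calls do not show an unstable change in the oxyR deletion.

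Genes of the Suf system, which assembles iron-sulfur clusters under stress, fell together in the oxyR deletion: 6 of 6 were lower, sufA from 2591 ± 166 to 788 ± 39.9 FPKM (SD, n = 2). Adjusted p was 6.15e-07 for the list and 0.0391 with an estimated correlation. The OxyR-activated list holds suf genes too, and both lists had a median of -1.52 on the log2 scale, so they are not separate results. In the Isc system, the housekeeping counterpart, 6 of 8 genes were higher, hscA by 1.18 and fdx by 1.18 on the log2 scale, and the fdx call was lost without library 1 of the oxyR deletion (adjusted p = 0.0587). Adjusted p was 0.000457 for the list and 0.0975 with an estimated correlation. In the RpoS general stress list 24 of 30 genes were lower and 1 was higher (26 and 1 adjusted over the list alone), among them osmC, which fell from 3953 ± 70.4 to 1748 ± 131 FPKM, and the DNA-binding protein gene dps, which fell from 23120 ± 724 to 9412 ± 345. Adjusted p was 2.03e-10 for the list and 0.0391 with an estimated correlation. In methionine biosynthesis 12 of 14 genes were lower and metH was higher (13 and 1 adjusted over the list alone), with metF falling from 139 ± 7.81 to 28.8 ± 4.18 FPKM and metK from 649 ± 34.2 to 177 ± 3.36. Adjusted p was 1.07e-08 for the list and 0.0561 with an estimated correlation. Iron uptake genes were lower in 18 of 36 cases and higher in 4 (20 and 4 adjusted over the list alone). The enterobactin synthesis gene entB fell by 1.40 on the log2 scale, while the ferrous iron importer gene feoB rose by 0.68. Adjusted p was 0.00127 for the list and 0.149 with an estimated correlation.

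Metal genes moved in both directions in the oxyR deletion. The zinc-binding protein genes zinT and znuA fell from 9269 ± 672 to 14.6 ± 2.60 FPKM and from 4937 ± 3.77 to 69.9 ± 5.06 FPKM (SD, n = 2), log2 changes of -9.22 and -6.12 (adjusted p = 8.57e-07 and 1.81e-07). The zinc importer genes znuB and znuC fell as well (log2 -2.24 and -2.90), and the zinc exporter gene zntA rose by 1.21. The short gene ykgM, which encodes a zinc-free form of ribosomal protein L31, fell from 19732 ± 1345 to 13.8 ± 12.5 FPKM, and rpmE, which encodes the zinc-binding form, rose from 131 ± 23.6 to 633 ± 140 FPKM (log2 2.26). The copper exporter genes cusF, cusB and cusA rose by 2.39, 2.10 and 2.03 on the log2 scale while the copper exporter gene copA and the copper oxidase gene cueO fell by 1.59 and 0.91. The copper and zinc list had 9 of 15 genes lower and 4 higher (10 and 4 adjusted over the list alone, adjusted p of the list = 0.00780, and 0.112 with an estimated correlation), and without genes under 300 bases, an alternative chosen after seeing the data, it no longer passed (adjusted p = 0.0529).

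Respiratory genes were higher in the oxyR deletion, with 17 of 29 genes of the aerobic respiration list higher and 1 lower (19 and 1 adjusted over the list alone), including the NADH dehydrogenase genes nuoC and nuoH (log2 0.74 and 0.75). Adjusted p was 2.86e-06 for the list and 0.0391 with an estimated correlation. Of the TCA cycle genes 9 of 17 were higher and 4 lower (adjusted p of the list = 0.0308, and 0.345 with an estimated correlation), a call lost without WT library 2 or library 1 of the oxyR deletion, with adjusted p up to 0.0774. Glycolytic genes were lower in 8 of 14 cases, gpmA falling from 5675 ± 132 to 2420 ± 47.0 FPKM (SD, n = 2). Adjusted p was 0.000689 for the list, 0.0776 with an estimated correlation and 0.166 under quantile normalization. Heat shock genes were higher in 9 of 17 cases and lower in 2, hslV by 0.87 and hslU by 0.78 on the log2 scale (3 lower adjusted over the list alone). Adjusted p was 0.00490 for the list and 0.171 with an estimated correlation. In purine and pyrimidine synthesis 11 of 22 genes were higher and 1 lower, with pyrB rising from 19.5 ± 0.995 to 78.2 ± 2.79 FPKM. Adjusted p was 0.0114 for the list and 0.112 with an estimated correlation. The branched-chain and leucine list had 9 of 17 genes higher and 3 lower, thrA by 0.85 on the log2 scale (4 lower adjusted over the list alone). Adjusted p was 0.0173 for the list and 0.388 with an estimated correlation.

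Genes of the SoxRS list split in the oxyR deletion, with 11 of 31 higher and 4 lower, also when adjusted over the list alone. The nitroreductase gene nfsA rose from 356 ± 24.8 to 579 ± 13.3 FPKM, while the fumarase gene fumC fell from 2096 ± 252 to 1086 ± 44.2 FPKM and the pyruvate oxidase gene poxB from 4629 ± 107 to 2365 ± 54.0 FPKM (SD, n = 2). The list did not pass (adjusted p = 0.102, and 0.512 with an estimated correlation), though it did with values as deposited (adjusted p = 0.0374) and under quantile normalization (adjusted p = 0.00490). The adhesin gene flu, known to be repressed by OxyR, rose from 407 ± 39.2 to 1396 ± 106 FPKM (log2 1.78), and the OxyR-repressed list as a whole, with 2 genes higher and 3 lower of 5, the deleted oxyR among the lower ones, did not pass (adjusted p = 0.281, and 0.959 without the deleted genes). The porin genes ompA and ompX fell by 0.40 and 0.48 on the log2 scale, a direction that turned under quantile normalization (log2 0.19 and 0.02), and neither passed with values as deposited. The ompA call was lost without library 1 or 2 of the oxyR deletion (adjusted p = 0.0784 and 0.0819) and the ompX call without library 2 (adjusted p = 0.0848).

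The test called 1124 of 3469 genes (32.4%) between the oxyR deletion and WT, 544 higher and 580 lower, and 109 of them changed by at least a doubling or halving. With values as deposited, which put the median of all genes at 0.174 on the log2 scale, the split was 1084 higher and 338 lower. Leaving out library 1 or 2 of the oxyR deletion lowered the count to 681 or 683. Among the 8 largest increases and decreases, valY, isrC and feoC were listed at 0 in both WT libraries and ykgO in both libraries of the oxyR deletion. The isrC call was lost in 3 of 8 fits that left out 1 library, with adjusted p up to 0.0652. valY is a tRNA gene with near-identical copies, so its values of 72190 and 41698 FPKM in the oxyR deletion are uncertain. ykgO, listed at 1033 and 2090 FPKM in WT, encodes a zinc-free form of ribosomal protein L36. The lysozyme inhibitor gene pliG fell from 1636 ± 235 to 80.5 ± 5.70 FPKM (SD, n = 2; log2 -4.32, adjusted p = 1.66e-05).

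The soxR deletion was compared with WT to ask which genes depended on SoxR. The superoxide response genes fell together. The fumarase gene fumC fell from 2096 ± 252 to 123 ± 0.430 FPKM and the flavodoxin reductase gene fpr from 5323 ± 247 to 378 ± 7.91 FPKM (SD, n = 2), log2 changes of -4.08 and -3.81 (adjusted p = 6.36e-06 and 1.32e-06). The manganese superoxide dismutase gene sodA fell from 20609 ± 730 to 2536 ± 17.4 FPKM (log2 -3.02), and the DNA repair gene nfo (log2 -2.82), the glucose-6-phosphate dehydrogenase gene zwf (log2 -1.83) and the aconitase gene acnA (log2 -2.01) fell as well. Among 31 measured genes of the SoxRS list, 26 were lower and none higher (28 adjusted over the list alone). Adjusted p was 8.86e-22 for the list and 0.0474 with an estimated correlation. The arylamine acetyltransferase gene nhoA, outside the list, fell from 1044 ± 258 to 41.4 ± 2.36 FPKM (log2 -4.60).

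Of the genes activated by OxyR, 8 of 20 were lower, also adjusted over the list alone, katG by 0.89 and trxC by 0.67 on the log2 scale, while yaiA fell by 2.72. Adjusted p was 0.00187 for the list and 0.103 with an estimated correlation. The Suf list did not pass (adjusted p = 0.948) and none of its 6 genes was called. Methionine biosynthesis genes were higher in 13 of 14 cases, metE from 2003 ± 165 to 6056 ± 148 FPKM and metF from 139 ± 7.81 to 596 ± 14.1 FPKM (SD, n = 2). Adjusted p was 9.63e-11 for the list and 0.0474 with an estimated correlation. Iron uptake genes were higher in 17 of 36 cases with none lower (20 adjusted over the list alone), exbB by 0.53 and exbD by 0.47 on the log2 scale. Adjusted p was 1.25e-07 for the list and 0.0606 with an estimated correlation. In the Isc system 5 of 8 genes were higher, iscR by 0.62. Adjusted p was 0.00158 for the list and 0.105 with an estimated correlation.

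Ribosomal protein genes were higher in 32 of 54 cases and lower in 1 (38 and 1 adjusted over the list alone), rpsS by 0.86 on the log2 scale and rplD from 1498 ± 46.0 to 2534 ± 84.7 FPKM (SD, n = 2), while rpmE fell by 1.29 on the log2 scale. Adjusted p was 9.88e-12 for the list and 0.103 with an estimated correlation. Purine and pyrimidine genes were higher in 15 of 22 cases (16 higher and 1 lower adjusted over the list alone), pyrB by 1.68 on the log2 scale. Adjusted p was 1.17e-06 for the list and 0.0474 with an estimated correlation. Heat shock genes were lower in 15 of 17 cases (16 adjusted over the list alone), the chaperone gene dnaK from 621 ± 10.8 to 368 ± 4.19 FPKM and groL from 961 ± 0.186 to 561 ± 25.3 FPKM. Adjusted p was 6.92e-09 for the list and 0.0474 with an estimated correlation. Aerobic respiration genes were lower in 15 of 29 cases, nuoC by 1.01 and nuoF by 1.02. Adjusted p was 2.11e-05 for the list and 0.0474 with an estimated correlation. TCA cycle genes were lower in 6 of 17 cases and higher in 1 (adjusted p of the list = 0.0102, 0.234 with an estimated correlation and 0.225 under quantile normalization). The median of that list was -0.165 and its mean -0.470 on the log2 scale, so a few large decreases weigh on the mean. Its members fumC and acnA, also on the SoxRS list, changed by -4.08 and -2.01, so the 2 lists are not separate results. The colanic acid capsule genes were higher in 5 of 8 cases, gmd from 3.28 ± 0.179 to 20.0 ± 3.88 FPKM. Adjusted p was 0.0111 for the colanic acid list and 0.234 with an estimated correlation. The porin gene ompF rose from 780 ± 41.6 to 2397 ± 34.8 FPKM (log2 1.62), and flu fell from 407 ± 39.2 to 155 ± 2.27 FPKM. The mandelate racemase family gene rspA rose from 5.26 ± 0.431 to 87.4 ± 1.84 FPKM (log2 3.82, adjusted p = 0.000591) and its neighbour rspB by 3.46.

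In the soxR deletion 998 of 3469 genes (28.8%) were called, 499 higher and 499 lower, and 125 changed by at least a doubling or halving. The split was 370 higher and 671 lower with values as deposited and 615 higher and 358 lower under quantile normalization. Leaving out library 1 of the soxR deletion lowered the count to 601. The call of ahpC, which fell by 0.34 on the log2 scale, turned under quantile normalization (log2 0.34) and was lost without either library of the oxyR or soxR deletion, with adjusted p up to 0.0753. Among the 8 largest changes each way, blr, mokB and feoC were listed at 0 in both WT libraries, and yabQ, yhfG and b4564 in both libraries of the soxR deletion. The blr and mokB calls were each lost in 6 of 8 fits that left out 1 library, with adjusted p up to 0.158 and 0.152.

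The soxS deletion was compared with WT to ask which genes depended on SoxS. The same list of superoxide response genes was lower. fumC fell to 45.1 ± 1.38 FPKM and sodA to 1628 ± 44.2 (SD, n = 2), log2 changes of -5.50 and -3.66 (adjusted p = 1.32e-06 for both). fpr fell as well (log2 -4.55, adjusted p = 6.50e-07). The pyruvate-flavodoxin oxidoreductase gene ydbK fell from 980 ± 4.40 to 75.5 ± 2.84 FPKM (log2 -3.68) and nhoA to 16.4 ± 1.35 FPKM (log2 -5.89). Of 31 genes on the SoxRS list 28 were lower, the deleted soxS among them, also adjusted over the list alone. Adjusted p was 1.88e-27 for the list and 0.0178 with an estimated correlation. The genes waaY, waaZ and marB did not pass.

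Zinc uptake genes were lower in the soxS deletion. zinT fell from 9269 ± 672 to 51.0 ± 0.524 FPKM, znuA from 4937 ± 3.77 to 395 ± 11.5 FPKM and ykgM to 32.7 ± 10.7 FPKM (SD, n = 2), log2 changes of -7.48, -3.64 and -9.23 (adjusted p = 1.41e-06, 1.32e-06 and 0.000443). ykgO was listed at 0 in both libraries, and rpmE rose by 1.81 on the log2 scale. In the copper and zinc list 11 of 15 genes were lower and none higher (11 and 1 adjusted over the list alone, adjusted p of the list = 9.72e-10, and 0.0178 with an estimated correlation), including copA (log2 -0.85) and cueO (log2 -0.97). In the soxR deletion znuA rose by 0.28, and zinT, znuB and znuC differed from WT by 0.34, -0.08 and -0.04 on the log2 scale (adjusted p = 0.0904, 0.275 and 0.617).

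**Figure D2:**
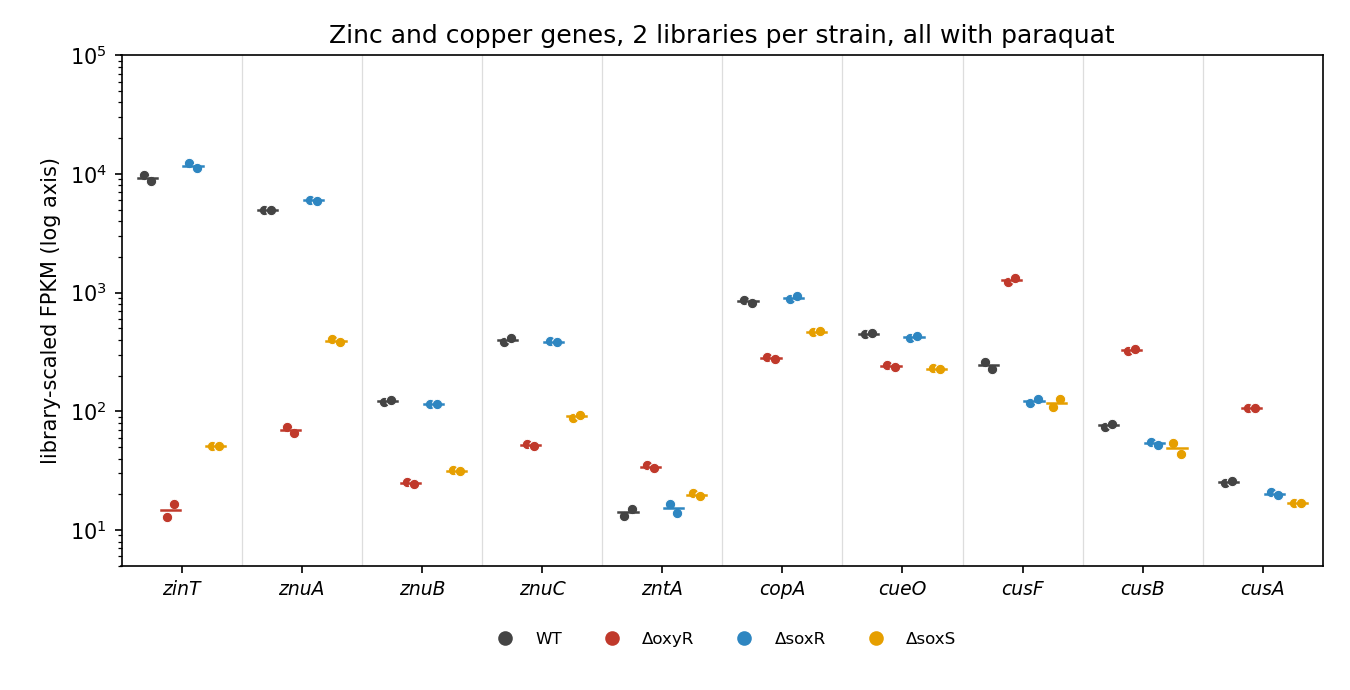
FPKM after library scaling (log axis) of 4 zinc uptake genes, the zinc exporter gene zntA and 5 copper genes in each of the 8 libraries, with bars at the mean of the 2 libraries of a strain. The zinT points are near 9269 FPKM in WT and 11744 in the soxR deletion, 14.6 in the oxyR deletion and 51.0 in the soxS deletion, and the cusF, cusB and cusA points are highest in the oxyR deletion.

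Methionine biosynthesis genes were higher in 12 of 14 cases in the soxS deletion (13 adjusted over the list alone), metK from 649 ± 34.2 to 1526 ± 57.4 FPKM and metF to 316 ± 10.2 FPKM (SD, n = 2). Adjusted p was 7.45e-11 for the list and 0.0361 with an estimated correlation. Purine and pyrimidine genes were lower in 14 of 22 cases (16 lower and 1 higher adjusted over the list alone), purT from 64.6 ± 1.90 to 19.0 ± 0.548 FPKM and purE and purM by 1.36 and 1.32 on the log2 scale. Adjusted p was 2.14e-09 for the list and 0.0178 with an estimated correlation. Aerobic respiration genes were lower in 21 of 29 cases and higher in 2 (22 and 2 adjusted over the list alone), cyoA by 0.85 on the log2 scale, and the higher ones, cydA and cydB, encode cytochrome bd oxidase. Adjusted p was 2.26e-09 for the list and 0.0178 with an estimated correlation. TCA cycle genes were lower in 7 of 17 cases (10 adjusted over the list alone), with a median of -0.228 and a mean of -0.600 on the log2 scale. Here too fumC and acnA (log2 -5.50 and -1.77) weigh on the mean of the list. Adjusted p was 8.21e-05 for the list and 0.121 with an estimated correlation. The RpoS list had 13 of 30 genes higher and 1 lower (15 and 2 adjusted over the list alone), otsB rising by 0.54 and poxB falling by 2.68 on the log2 scale. Adjusted p was 0.000312 for the list and 0.121 with an estimated correlation. The OxyR-activated list had 8 of 20 genes lower and 1 higher (10 and 1 adjusted over the list alone). Adjusted p was 0.000378 for the list and 0.0901 with an estimated correlation. The pentose phosphate list had 7 of 15 genes lower and 2 higher (8 and 2 adjusted over the list alone, adjusted p of the list = 0.0298, 0.189 with an estimated correlation and 0.0693 under quantile normalization), a call lost without WT library 1 (adjusted p = 0.0526) or library 2 of the soxS deletion (adjusted p = 0.0599). The SOS list had 3 of 18 genes higher (adjusted p of the list = 0.0153, and 0.189 with an estimated correlation), among them sulA (log2 0.49), whose call was lost without library 2 of the soxS deletion (log2 0.41).

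The ribosomal list in the soxS deletion had a median of -0.11 and a mean of 0.12 on the log2 scale, with 6 of 54 genes lower and 1 higher, and its call (adjusted p = 0.0401) was lost with an estimated correlation (adjusted p = 0.534) and turned direction under quantile normalization (adjusted p = 0.246) and did not pass with values as deposited (adjusted p = 0.0750). Without WT library 2, or library 1 or 2 of the soxS deletion, its adjusted p was 0.201, 0.0571 or 0.119. ompF rose from 780 ± 41.6 to 1590 ± 27.0 FPKM and flu fell to 104 ± 2.10 FPKM (SD, n = 2). The test called 634 of 3469 genes (18.3%) between the soxS deletion and WT, 274 higher and 360 lower, and 106 changed by at least a doubling or halving. The split was 353 higher and 318 lower with values as deposited and 382 higher and 280 lower under quantile normalization. Leaving out library 1 or 2 of the soxS deletion lowered the count to 306 or 351.

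Of the lists that passed against WT, those whose call held with an estimated correlation were OxyR-activated, Suf, RpoS and aerobic respiration in the oxyR deletion. In the soxR deletion they were SoxRS, methionine, heat shock, purine and pyrimidine, and aerobic respiration, and in the soxS deletion SoxRS, methionine, copper and zinc, purine and pyrimidine, and aerobic respiration. A call lost with an estimated correlation does not by itself show correlated genes, because that test also has fewer degrees of freedom. The lists of cysteine synthesis, anaerobic respiration, multidrug efflux, porins, flagella, type 1 fimbriae, histidine, tryptophan and arginine synthesis, manganese and superoxide dismutase, and thiol redox genes passed in no deletion against WT (adjusted p from 0.0577 to 0.981). Leaving out 1 library let the fimbriae and manganese lists pass in the soxR deletion (without its library 2 and without WT library 2, lowest adjusted p = 0.0301 and 0.0149). It let the anaerobic list pass in the soxS deletion without library 1 or 2 of the soxR deletion (lowest adjusted p = 0.0435). Single genes in them did pass: the tryptophan gene trpA rose by 0.92 in the oxyR deletion and fell by 0.67 and 0.68 in the soxR and soxS deletions, and the transcription factor gene rob rose by 0.98 and 1.25 in the soxR and soxS deletions on the log2 scale. The iron superoxide dismutase gene sodB stood at 21.7 ± 6.59 FPKM in WT and 55.4 ± 5.22 in the oxyR deletion (SD, n = 2; log2 1.34, adjusted p = 0.0142), a call lost without library 1 or 2 of the oxyR deletion, with adjusted p up to 0.0779.

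**Figure D3:**
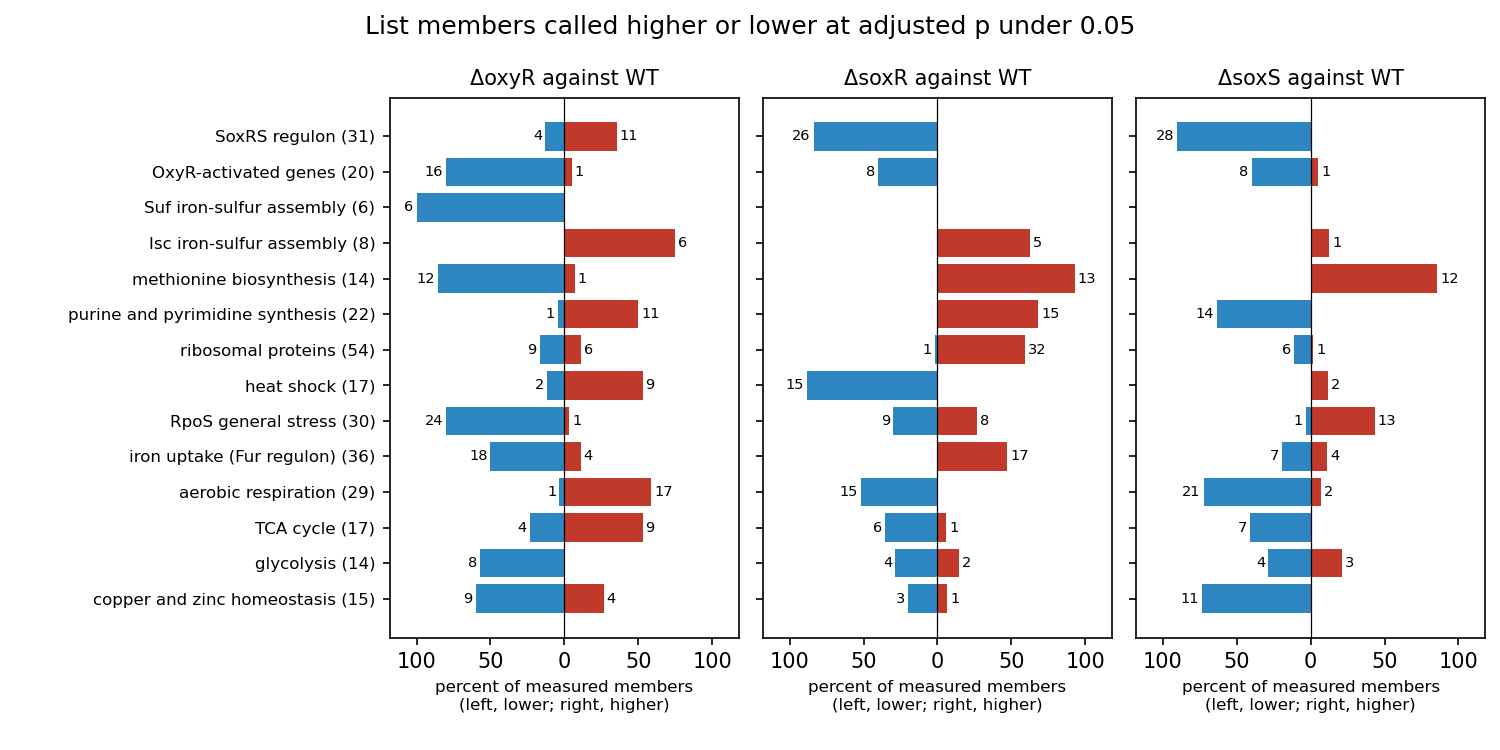
Percent of the measured genes of 14 fixed lists that were called lower (left) or higher (right) than WT in the oxyR, soxR and soxS deletions, with the number of genes at each bar. The SoxRS list has 26 of 31 genes lower in the soxR deletion and 28 in the soxS deletion, against 4 in the oxyR deletion.

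The 2 sox deletions were compared with each other to test where loss of the sensor and loss of the activator differed. Several superoxide response genes were lower still without soxS: fumC by 1.42, fpr by 0.74, sodA by 0.64 and ydbK by 0.53 on the log2 scale, with sodA at 1628 ± 44.2 FPKM in the soxS deletion and 2536 ± 17.4 in the soxR deletion (SD, n = 2; adjusted p = 0.00157). The sodA call was lost under quantile normalization (log2 -0.45). inaA (log2 0.08), nfsA (log2 -0.01) and poxB (log2 0.02) did not pass (adjusted p = 0.605, 0.937 and 0.781). In the SoxRS list 8 of 31 genes were lower in the soxS deletion, the deleted soxS among them, and 1 was higher (10 and 1 adjusted over the list alone). Adjusted p was 0.0165 for the list and 0.358 with an estimated correlation. That call was lost without the deleted genes (adjusted p = 0.0557), with values as deposited (0.0640), under quantile normalization (0.0762), without library 1 of the soxR deletion (0.123) and without library 2 of the soxS deletion (0.0565).

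Ribosomal protein genes were lower in the soxS deletion than in the soxR deletion in 41 of 54 cases and higher in 1 (47 and 2 adjusted over the list alone), rpsS at 1663 ± 210 against 3090 ± 232 FPKM (SD, n = 2). Adjusted p was 4.81e-16 for the list and 0.0945 with an estimated correlation. Purine and pyrimidine genes were lower in 19 of 22 cases (20 lower and 1 higher adjusted over the list alone), pyrB at 16.4 ± 0.606 against 64.9 ± 9.30 FPKM. Adjusted p was 7.33e-14 for the list and 0.0286 with an estimated correlation. Heat shock genes were higher in 15 of 17 cases (16 adjusted over the list alone), ibpA by 1.34 and dnaK by 1.12 on the log2 scale. Adjusted p was 5.57e-11 for the list and 0.0516 with an estimated correlation. Iron uptake genes were lower in 14 of 36 cases (17 adjusted over the list alone), cirA by 0.88 (adjusted p of the list = 1.39e-07, and 0.0897 with an estimated correlation), and RpoS genes were higher in 14 of 30 cases and lower in 2 (14 and 4 adjusted over the list alone). Adjusted p was 0.000349 for the RpoS list and 0.157 with an estimated correlation. In the copper and zinc list 9 of 15 genes were lower (10 lower and 1 higher adjusted over the list alone), zinT at 51.0 ± 0.524 against 11744 ± 785 FPKM. Adjusted p was 7.39e-07 for the list and 0.0516 with an estimated correlation. The Isc list had 5 of 8 genes lower (6 adjusted over the list alone, adjusted p of the list = 0.00361, and 0.160 with an estimated correlation) and the colanic acid list 3 of 8 (5 adjusted over the list alone). Adjusted p was 0.00691 for the colanic acid list and 0.267 with an estimated correlation. The test called 813 of 3469 genes (23.4%), 367 higher and 446 lower, and the split was 698 higher and 303 lower with values as deposited, which put the median of all genes at 0.130 on the log2 scale. Leaving out 1 library lowered the count to 412 or 500 without library 1 or 2 of the soxR deletion and to 400 or 399 without library 1 or 2 of the soxS deletion.

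**Figure D4:**
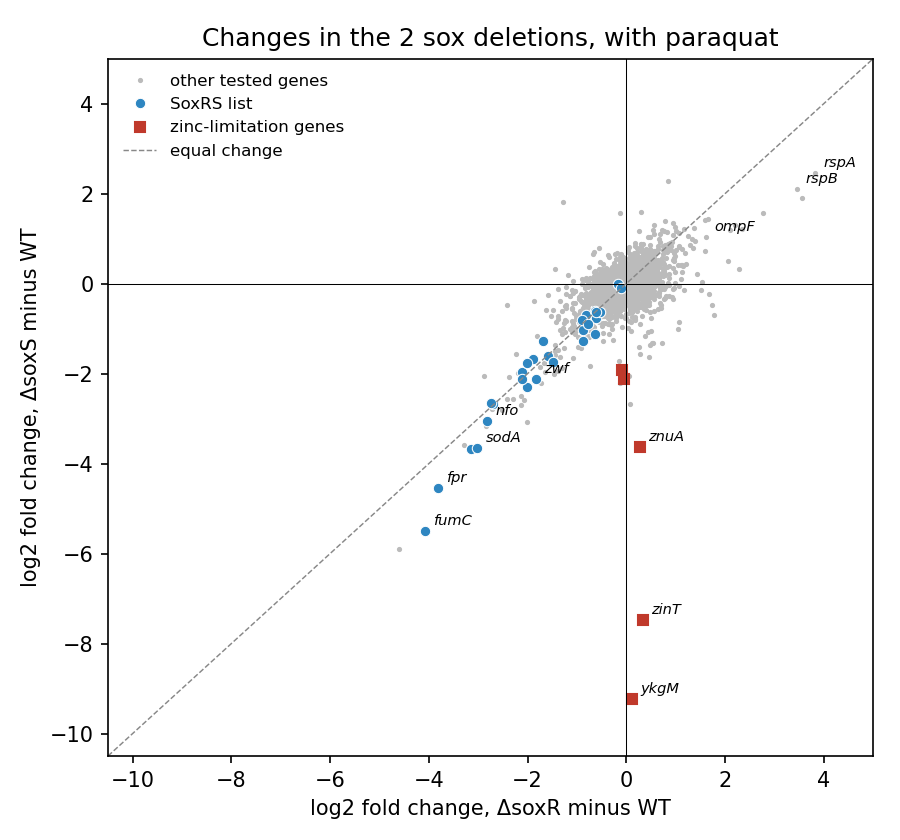
Log2 change against WT in the soxR deletion (x axis) and the soxS deletion (y axis) for 3323 tested genes with values above 0 in every library, with 29 SoxRS list genes in blue, zinT, znuA, znuB, znuC and ykgM as red squares and a dashed line at equal change. The SoxRS genes fumC and fpr lie at -4.08 and -3.81 in the soxR deletion and at -5.50 and -4.55 in the soxS deletion, and zinT lies at 0.34 and -7.48.

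The oxyR deletion was compared with each sox deletion to separate genes that depend on OxyR from those that depend on SoxR or SoxS. SoxRS genes were higher in the oxyR deletion than in the soxR deletion in 27 of 31 cases and than in the soxS deletion in 28, the deleted soxS among them, with the same counts adjusted over the list alone. Adjusted p was 9.62e-18 and 2.26e-17 for the list, and 0.0470 and 0.0363 with an estimated correlation. fumC stood at 1086 ± 44.2 FPKM in the oxyR deletion and 45.1 ± 1.38 in the soxS deletion (SD, n = 2), a log2 difference of 4.56 (adjusted p = 2.48e-06). OxyR-activated genes were lower in 14 of 20 cases and higher in 3 in both comparisons (16 lower against the soxS deletion adjusted over the list alone, adjusted p of the list = 2.73e-06 and 3.51e-06, and 0.0470 and 0.0363 with an estimated correlation), and 6 of 6 Suf genes were lower in both. grxA stood at 76.6 ± 18.9 FPKM in the oxyR deletion and 1372 ± 8.07 in the soxS deletion. Against the soxR deletion, zinT and znuA differed by -9.56 and -6.40 on the log2 scale (adjusted p = 4.57e-07 and 1.06e-07). Against the soxS deletion, rspA and rspB were lower by log2 differences of -3.96 and -3.85, with rspA at 1.31 ± 1.00 FPKM in the oxyR deletion.

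Methionine genes were lower in the oxyR deletion than in either sox deletion, 13 of 14 in both comparisons with 1 higher, metF by log2 differences of -4.33 and -3.42 (adjusted p = 2.85e-06 and 9.56e-06). Aerobic respiration genes were higher in 23 and 25 of 29 cases with 1 lower, nuoC by 1.75 and 1.45 on the log2 scale. RpoS genes were lower in 19 of 30 cases and higher in 3 against the soxR deletion (adjusted p of the list = 5.11e-05, and 0.0907 with an estimated correlation), and lower in 27 and higher in 2 against the soxS deletion. Against the soxR deletion, heat shock genes were higher in 14 of 17 cases (15 adjusted over the list alone), dnaK at 846 ± 26.7 against 368 ± 4.19 FPKM (SD, n = 2). Iron uptake genes were lower in 21 of 36 cases there and higher in 1, entB by a log2 difference of -1.60 (adjusted p of the list = 3.39e-07, and 0.0579 with an estimated correlation). Ribosomal protein genes were lower in 30 of 54 cases and higher in 1 (32 and 2 adjusted over the list alone, adjusted p of the list = 7.94e-07, and 0.177 with an estimated correlation), a call lost under quantile normalization. Colanic acid genes were lower in 5 of 8 cases (adjusted p of the list = 0.00937, and 0.179 with an estimated correlation), and the copper and zinc list had 9 of 15 genes lower and 4 higher. Adjusted p was 0.0151 for the copper and zinc list, 0.133 with an estimated correlation and 0.0833 without genes under 300 bases. Against the soxS deletion, purine and pyrimidine genes were higher in 18 of 22 cases and lower in 1, pyrB at 78.2 ± 2.79 against 16.4 ± 0.606 FPKM. Isc genes were higher in 6 of 8 cases and lower in 1 (adjusted p of the list = 0.0180, and 0.216 with an estimated correlation), and iron uptake genes lower in 18 of 36 and higher in 4. Adjusted p was 0.0109 for the iron list and 0.227 with an estimated correlation.

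The test called 1356 genes between the oxyR and soxR deletions (39.1%), 685 higher and 671 lower in the oxyR deletion, and 1480 between the oxyR and soxS deletions (42.7%), 753 higher and 727 lower. With values as deposited, which put the median of all genes at 0.274 and 0.140 on the log2 scale, the splits were 1383 higher and 342 lower, and 1072 higher and 507 lower. Among the 5 largest differences each way, valY, yabQ, yhfG, isrC (call lost without library 1 of the oxyR deletion, adjusted p = 0.0539) and an unnamed gene (call lost in 6 of 8 fits that left out 1 library, adjusted p up to 0.184) were listed at 0 in both libraries of the soxR deletion, valY and the deleted soxS in both libraries of the soxS deletion, and ykgO in both libraries of the oxyR deletion.

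The calls against WT overlapped most between the 2 sox deletions. There 147 genes were higher in both and 211 lower in both, 358 in all, and 55 were called in opposite directions, while lists drawn independently would share 39.4 higher and 51.8 lower genes. The oxyR and soxR deletions shared 155 higher and 144 lower genes (independent lists 78.2 and 83.4) with 223 opposite, and the oxyR and soxS deletions shared 55 higher and 91 lower genes (independent lists 43.0 and 60.2) with 230 opposite. For the oxyR and soxS deletions, opposite calls thus outnumbered the 146 in the same direction. Counts for independent lists were not computed for opposite calls. In 100 simulations of unchanged groups that shared a simulated WT group, at most 1 gene was shared. Groups with no change give almost no calls, so this is no measure of the overlap that shared controls add among real changes. All libraries of a simulation, WT included, were drawn around the WT means, so the deviations of the measured WT libraries are not in it. Both WT libraries enter every one of these comparisons, so part of the excess in the same direction may come from the shared controls. Across 3323 genes with values above 0 in every library, a set chosen after seeing the data, the covariance of log2 changes was 0.156 between the sox deletions (0.0166 simulated), 0.0661 between the oxyR and soxS deletions (0.0166 simulated) and 0.0063 between the oxyR and soxR deletions (0.0167 simulated), with correlations across genes, which are not independent replicates, of 0.605, 0.227 and 0.0225 (0.502, 0.502 and 0.505 simulated). A covariance is weighted by the largest changes, and zinT, znuA and ykgM fell strongly in both the oxyR and soxS deletions. It was not computed without these genes, so the value for that pair does not show a similarity across most genes. Over all 3469 tested genes, zeros included, the covariances were 0.350, 0.289 and 0.318 (0.317, 0.317 and 0.317 simulated). Leaving out 1 library lowered the overlap of the sox deletions to 195 or 229 (soxS deletion library 1 or 2), that of the oxyR and soxR deletions to 174, 156, 173 or 192 (oxyR deletion library 1 or 2, soxR deletion library 1 or 2) and that of the oxyR and soxS deletions to 96, 93, 78 or 85 (oxyR deletion library 1 or 2, soxS deletion library 1 or 2). The same direction was called in 90 genes in all 3 deletions, 38 higher and 52 lower.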

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

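The tests that weigh explanations below were chosen only after the results were seen. In 12 cases a gene list changed in opposite directions against WT in a pair of deletions, both changes were called, and the difference between the deletions was called as well. Values are the median log2 difference of the list, followed by its adjusted p and the adjusted p with an estimated correlation. Between the oxyR and soxR deletions these were iron uptake (-0.516, 3.39e-07 and 0.0579), methionine synthesis (-1.62, 7.61e-10 and 0.0470), the TCA cycle (0.483, 0.000108 and 0.122), aerobic respiration (0.579, 8.92e-09 and 0.0470) and heat shock (0.806, 6.80e-08 and 0.0493). Between the oxyR and soxS deletions they were methionine synthesis (-1.62, 2.68e-09 and 0.0363), the TCA cycle (0.654, 6.15e-05 and 0.121), aerobic respiration (0.751, 1.84e-09 and 0.0363), RpoS (-0.817, 1.84e-09 and 0.0363) and purine and pyrimidine synthesis (0.768, 1.24e-07 and 0.0363). Between the soxS and soxR deletions they were ribosomal proteins (-0.446, 4.81e-16 and 0.0945) and purine and pyrimidine synthesis (-1.15, 7.33e-14 and 0.0286). With an estimated correlation both opposite changes against WT kept their call in only 3 of the 12 cases: aerobic respiration in both comparisons of the oxyR deletion, and purine and pyrimidine synthesis between the sox deletions. The TCA cycle list shares fumC and acnA with the SoxRS list, and these genes weigh on its mean in both sox deletions. The ribosomal list is the weakest case, since its change in the soxS deletion had a median of -0.108 but a mean of 0.117, adjusted p = 0.534 with an estimated correlation, a direction that turned under quantile normalization and a call lost in 3 of 8 fits that left out 1 library. A change in opposite directions is therefore not shown for it.

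The zinc uptake genes zinT, znuA, znuB and znuC were lower than WT in the oxyR and soxS deletions but not in the soxR deletion. Library scaling or a single library is an unlikely cause, because the change closest to 0 over other scalings and left-out libraries was still -1.86 on the log2 scale. A dependence on SoxS that the soxS transcript left in the soxR deletion would meet was not tested and stays open for the soxS deletion. Zinc available to the cultures stays open: the exporter gene zntA rose in the oxyR deletion, but its 0.460 in the soxS deletion did not pass (adjusted p = 0.0541). Zinc was not measured, and a difference between cultures could not be separated from the deletion.

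Genes of the SoxRS list, among them sodA, zwf, fumC, fpr, fldA, fldB and ydbK, were lower in the soxS deletion than in the soxR deletion, though fldA lost its call in 2 of 8 fits that left out 1 library (adjusted p up to 0.0587). Under both other scalings fumC, fpr and zwf kept their calls, and sodA (log2 -0.45) and fldA lost theirs under quantile normalization only. Whether scaling shifted the list as a whole stays open, since the list did not pass with values as deposited, under quantile normalization or without the deleted genes (adjusted p = 0.0640, 0.0762 and 0.0557). Without the deleted genes the list median was -0.0584 on the log2 scale in the main fit. With values as deposited the list median was 0.0529. That change of sign follows the library factor, since the median of all genes moved from 0.0226 to 0.130 as well. Under quantile normalization the list median was -0.0858. The soxS transcript left in the soxR deletion may explain the lower genes, and the Spearman correlation between dependence on SoxS and the difference was 0.414 (permutation p = 0.024, 30 genes, 100000 permutations), while the Pearson correlation was 0.290 (p = 0.11). Dependence was WT minus the soxS deletion in libraries 1, and the difference was the soxR minus the soxS deletion in libraries 2. Both hold the soxS deletion, so a drop particular to that strain would also raise the correlation. The rule that both must pass was set after the result was seen, genes are not independent, and the question stays open: inaA and poxB depended strongly on SoxS, yet their difference between the sox deletions did not pass.

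The ribosomal protein, nucleotide synthesis and heat shock lists differed between the soxS and soxR deletions at the preset correlation, and with an estimated correlation only the nucleotide list passed (adjusted p = 0.0945, 0.0286 and 0.0516). The 3 lists kept their calls under other scalings, with a largest adjusted p of 1.91e-09 at the preset correlation. The list test sets list genes against all other genes, so a factor common to a whole library largely cancels. Values as deposited are therefore a weak test of scaling as a cause. The growth state of the cultures could move these lists and stays open: list medians differed by at most 0.0867 between the 2 libraries of a strain, but growth state would be confounded with strain.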

How the results depend on the processing

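Counts of called genes ran from 681 to 1055 (oxyR deletion against WT), 601 to 869 (soxR), 306 to 546 (soxS), 399 to 878 (soxS against soxR deletion), 945 to 1399 (oxyR against soxR) and 1098 to 1503 (oxyR against soxS) when 1 library was left out, where the lone library is assumed to vary like the others. Called lists ran from 12 to 13, 11 to 13, 10 to 12, 8 to 10, 12 to 12 and 10 to 12 in the same order, and overlaps from 156 to 295 (oxyR and soxR), 78 to 155 (oxyR and soxS) and 195 to 325 (soxR and soxS). With only the 4 samples compared, the counts against WT were 746, 506 and 309, from fewer samples. Fits with fewer samples have less power, so lower counts in them do not by themselves show unstable changes. Requiring a doubling or halving left 109, 125, 106, 69, 285 and 265 genes. With an estimated correlation 4, 5, 5, 1, 6 and 7 lists passed. The replicate number as a block gave 1022, 917, 549, 724, 1284 and 1431 genes. Deviations of same-numbered libraries correlated at -0.111 to 0.151, highest between the oxyR and soxS deletions. With 2 libraries per strain, these values cannot exclude that same-numbered libraries shared a day or batch. Under quantile normalization the direction turned for zwf, ompX and ompA in the oxyR deletion (0.182, 0.0189 and 0.186), ahpC in the soxR deletion (0.337) and the ribosomal list in the soxS deletion (adjusted p = 0.246), and the cause was not tested. Of 427 gene values, quantile normalization kept 382 on their side of the threshold, values as deposited 406, the block 401 and the 4 samples compared 356. Depth limits genes of 1 kb near 0.456 to 0.704 FPKM and shorter genes at higher values, and 95.5% of genes under 100 bases were listed at 0 in some library.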

Other observations

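The genes in this part were picked and their tests chosen only after the values were seen. Among genes of 300 bases or more with at least 10 FPKM in WT, 44 were called and at least halved in both sox deletions, the deleted soxS among them, and 28 of the 44 lie outside the SoxRS list. Of these 28, 7 were lower, 5 higher and 16 not called in the oxyR deletion, and none was halved there. Some of the 28 carry IDs next to those of SoxRS list genes, such as yeiI beside nfo and ltaE beside poxB. The glycyl radical family gene yjjI fell from 46.5 ± 0.223 FPKM to 3.88 ± 0.0344 in the soxR deletion and 3.01 ± 0.694 in the soxS deletion (SD, n = 2), and the kinase family gene yeiI from 406 ± 0.921 to 55.7 ± 1.61 and 44.8 ± 7.55 FPKM. The cysteine detoxification regulator gene decR fell by 2.52 and 2.80 on the log2 scale, the transporter genes mdlA by 2.04 and 2.31 and mdlB by 2.13 and 2.49, and the murein transglycosylase gene mltC by 2.07 and 2.58. The nitroreductase gene nfsB fell by 1.25 and 1.43, the heme synthesis gene hemB by 1.44 and 1.37, and the lipid A synthesis gene lpxC by 1.38 and 1.48.

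Some genes outside the lists moved in opposite directions in the oxyR and soxR deletions. The hexuronate catabolism genes uxaA and uxaC fell by 2.11 and 2.24 on the log2 scale in the oxyR deletion and by 0.86 and 1.00 in the soxS deletion, and rose by 1.07 and 1.04 in the soxR deletion. The aromatic amino acid synthesis genes aroF and tyrA rose by 1.37 and 1.24 in the oxyR deletion and fell by 1.52 and 1.38 in the soxR deletion. The murein endopeptidase gene mepM, next to znuA, fell from 411 ± 8.45 to 36.5 ± 1.85 FPKM in the oxyR deletion and 63.9 ± 3.49 in the soxS deletion (SD, n = 2), and stood at 436 ± 4.18 in the soxR deletion (adjusted p = 0.322).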
